A study of Mus musculus with 13 samples.

How the data were processed

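Liver RNA from 13 mice on the C57BL/6J background was profiled on whole-transcript Affymetrix arrays, 1 array per liver. The mice were wild type or lacked Sel1L in hepatocytes, through a floxed exon 6 of Sel1l and Cre recombinase driven by the albumin promoter. Livers were taken at 3 and 9 weeks of age after a morning fast of 5 to 6 hours. Per the labels' protocols, RNA with an integrity number above 8 was accepted, and 100 ng per liver went into the sense-target labelling of the array supplier.

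The values analysed were the authors' deposited log2 expression values, 1 per array feature and liver, made by robust multi-array averaging (RMA) per the submitters' processing notes. RMA corrects the background, quantile-normalizes the probe values of the arrays and summarises the probes of a feature. A shift common to most genes would thus have been largely removed. The feature values of the arrays still differ slightly in distribution, as the medians below show. Its version, the software and the probe set definition were not given in the sources used here. The table held 35556 features with no missing value, between 0.405 and 13.62 on the log2 scale, and the array medians lay between 3.72 and 3.81. It carried no detection calls, so that no feature was called above or below background. A difference to or from a level below the array medians is a lower bound where that level is background. The array scans were not used here.

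Features were named from the platform annotation. Of the 35556 features, 21218 had 1 gene symbol, 1881 had several and 12457 (35.03%) were not listed there, which leaves them unnamed here. Whether these hold control features was not given in the sources used here, and counts over all features include them. The features with 1 symbol stood for 18820 genes, of which 1386 had more than 1 feature. Their gene numbers were looked up in a RefSeq gene table (assembly GRCm38.p6), where 21185 of the 21218 matched and 0 symbols needed an update. A gene with several features was represented by the one with the highest mean over the 13 livers. No genome build was named for the array, so no coordinates are given. Members of near-identical families (Cyp4a12a and Cyp4a12b, the Mup, Cyp2a, Cyp2b and Cyp3a genes) can share probe signal and are uncertain one by one.

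Groups and replicate numbers came from the sample titles: wild type at 3 weeks (n = 3), Sel1L-deficient at 3 weeks (n = 4), wild type at 9 weeks (n = 3) and Sel1L-deficient at 9 weeks (n = 3). The array descriptions of both 9-week livers titled replicate 3 carry another replicate number, and the titles were used. The numbering of the arrays skips 1 number within each 9-week group, so whether a further liver of each group was left out of the deposit is not known, and the 9-week count depends on single livers (18 to 1178 features with 1 left out). The labels describe separate mice and give neither litter nor hybridisation date. The descriptions also name 2 plate columns, 5 and 7, each with livers of every group, which served as a technical batch. The number of arrays limits the precision: the median within-group SD of a feature was 0.153, 0.156, 0.150 and 0.148 log2 units in the 4 groups in the order above.

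Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 13 livers, then eBayes, two-sided). P-values were adjusted by Benjamini-Hochberg over all 35556 features, and an adjusted p under 0.05 counted as changed. The contrasts were Sel1L-deficient against wild type at each age, the difference of these effects between ages (the interaction), and 9 against 3 weeks in each genotype. SE and adjusted p of single genes come from this fit. In addition, 31 gene lists (pathways, sex-biased genes and markers of other cell types), with at least 5 measured members each, were tested with camera at a preset inter-gene correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which asks whether the members move one way on balance and sets no list against other genes. Counts within a list are given over all features and adjusted over the list alone. Aliases in the lists were matched to the annotation's symbols. Some lists share members, such as G6pc and Pck1 in the CREBH-type and gluconeogenesis lists. Cyp7b1 and Slco1a1 are in both the male-biased and the bile acid list. Counts of called lists are therefore not counts of independent results.

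Design, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Sel1l, Syvn1, Fgf21 and Creb3l3 throughout. For each genotype comparison it took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, leaving out predicted genes, receptor families, small RNAs and antigen receptor segments. It took 6 per direction for wild-type ageing, 5 per direction for the interaction, up to 6 genes called at both ages, and from each list up to 4 members with the smallest p. Other members are named where they complete a count of called genes.

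The fit was tested on simulated arrays with each feature's own mean and residual spread. In the 3-week comparison it recovered 82 of 100 genes changed by 1 log2 unit and 99 of 100 changed by 2, and 17 of 203 calls were false. In the 9-week comparison it recovered 82 of 100 and 100 of 100, and 9 of 195 calls were false. A list shifted by 0.5 log2 units was called in both simulations, and 0 of the 30 other lists were. The simulated noise was independent between genes, which real noise is not. The changed genes were drawn at random whatever their spread, and having many of them eases the Benjamini-Hochberg threshold. These shares are therefore not the power of the real comparisons. In the real 3-week data Sel1l and Derl3 differed by more than 1 log2 unit and were not called over all features.

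The alternatives were a filter that removed the 40% dimmest features, features with 1 symbol only, renewed quantile normalization, median centring, eBayes with trend and robust settings, a fit of the compared groups alone, array weights, plate column as a covariate, a replicate block, an adjusted p under 0.01, a minimum fold of 1.5, camera on ranks, and leaving out each liver in turn. A change of sign was counted as a reversal only where the value was called in either fit. Figures were drawn with matplotlib 3.10.9.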

Results

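The series profiled livers of wild-type mice and of mice lacking Sel1L in hepatocytes, at 3 weeks (around weaning) and at 9 weeks (young adult). Sel1L is the adaptor of the ubiquitin ligase Hrd1 in endoplasmic reticulum-associated degradation (ERAD), which removes misfolded proteins from the endoplasmic reticulum (ER). The series' title ties this pathway to the hormone FGF21 and to CREBH, an ER-bound transcription factor of hepatocytes. There were 3 wild-type and 4 Sel1L-deficient livers at 3 weeks, and 3 of each genotype at 9 weeks. The values are RMA log2 expression, with 35556 features per array. Arrays of the same group correlated between 0.9828 and 0.9884 across features, and arrays of different groups between 0.9761 and 0.9871, so no liver appeared to be deposited in duplicate.

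Sel1l itself (feature 10401900) was lower in each Sel1L-deficient liver than in any wild-type liver of its age. At 3 weeks the wild-type livers stood at 8.94, 8.77 and 8.85 and the Sel1L-deficient livers at 8.42, 7.90, 7.20 and 7.10 on the log2 scale. At 9 weeks the values were 8.78, 8.70 and 8.72 against 7.90, 7.54 and 7.72. The log2 differences were -1.21 ± 0.26 (SE; 0.434-fold, adjusted p = 0.391) and -1.02 ± 0.28 (0.494-fold, adjusted p = 0.108), neither past the threshold over all features. Which exons the probes of this feature cover was not given in the sources used here. A transcript that lacks exon 6 can still hybridise elsewhere, and other liver cells keep the gene. Within plate columns 5 and 7 the Sel1l difference was -1.40 and -0.96 at 3 weeks, and -0.89 and -1.21 at 9 weeks. Column 7 at 3 weeks and column 5 at 9 weeks each held 1 wild-type liver. Column 7 at 9 weeks held 1 Sel1L-deficient liver.

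Among the other genes of the study's title, Syvn1, which encodes Hrd1, rose 3.24-fold at 9 weeks (7.90 ± 0.10 to 9.60 ± 0.65, mean ± SD, n = 3 each; adjusted p = 0.0154). At 3 weeks its log2 difference was 0.54 ± 0.24 (SE; adjusted p = 0.670). Fgf21 stood at 5.94 ± 0.64 in wild type and 8.90 ± 0.14 in Sel1L-deficient liver at 9 weeks, a 7.77-fold difference without overlap that missed the threshold (adjusted p = 0.0695). At 3 weeks Fgf21 was 7.21, 7.19 and 7.09 in wild type and 7.96, 9.30, 6.14 and 5.96 in the Sel1L-deficient livers, with values on both sides of wild type. The log2 difference there was 0.18 ± 0.66 (SE; adjusted p = 0.970). Creb3l3, the gene of CREBH, differed by -0.22 ± 0.14 at 3 weeks and 0.05 ± 0.15 at 9 weeks (SE; adjusted p = 0.763 and 0.930), with SDs between 0.167 and 0.213 within groups.

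**Figure D1:**
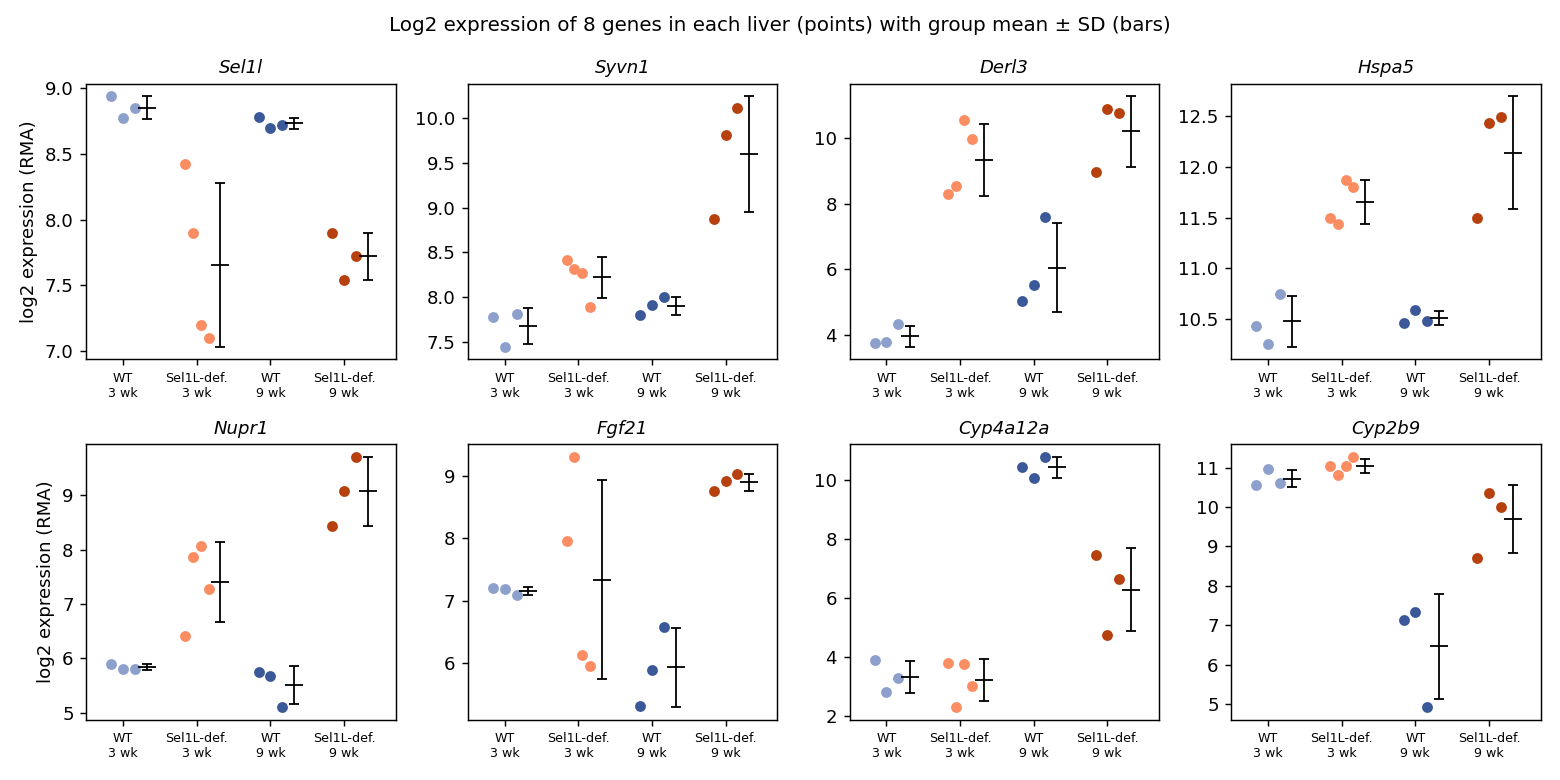
Log2 expression (y axis) of 8 genes in each liver (points) of the 4 groups (x axis), with group mean ± SD beside them. Sel1l was lower in all Sel1L-deficient livers, Syvn1, Nupr1 and Cyp2b9 rose and Cyp4a12a fell at 9 weeks, and the 4 Fgf21 values of the 3-week Sel1L-deficient livers ran from 5.96 to 9.30.

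The 3-week comparison asks what loss of Sel1L changes in young liver. ER chaperones and folding enzymes were higher as a group. Their median log2 difference was 0.475, 21 of 25 measured members lay above 0, and 16 rose when adjusted over the list alone, against 0 over all features. Hspa5, the main ER chaperone, stood at 10.48 ± 0.25 (SD, n = 3) in wild type and 11.65 ± 0.21 (n = 4) in Sel1L-deficient liver, a 2.25-fold difference. Sdf2l1, Pdia6 and Hsp90b1, all ER folding factors, differed by 2.25 ± 0.47, 1.26 ± 0.25 and 1.24 ± 0.26 on the log2 scale (SE), and none of their values overlapped between groups. Camera called the list (adjusted p = 1.93e-16), but not with an estimated correlation (adjusted p = 0.360 with an estimated correlation), and fry gave an adjusted p of 0.119. The list's median difference was 0.49 within plate column 5 and 0.48 within column 7, which held 1 wild-type liver of this age.

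Derl3, a member of the Derlin family of ERAD, showed the largest difference of the named genes, from 3.96 ± 0.31 to 9.35 ± 1.09 (SD; 41.8-fold; adjusted p = 0.186). ERAD components as a list had a median of 0.079, with 2 members that rose (Derl3 and Erlec1) and 1 that fell (Sel1l) adjusted over the list alone. ER translocation, glycosylation and transport genes, typical targets of XBP1, had a median of 0.216, 28 of 29 members above 0, and 2 that rose adjusted over the list alone (Srprb, 0.49 ± 0.11, and Kdelr2, 0.47 ± 0.11, SE). Camera called both lists upward (adjusted p = 0.000452 and 2.25e-08), but neither with an estimated correlation (adjusted p = 0.379 for each with an estimated correlation). Targets of the integrated stress response were not called (camera adjusted p = 0.787; median -0.026, mean 0.084). Nupr1, a stress-inducible regulator in that list, rose adjusted over the list alone, with a log2 difference of 1.57 ± 0.38 (SE). Among p53 targets (median 0.083), Zmat3 (0.43 ± 0.11) and Ccng1 (0.51 ± 0.14) rose adjusted over the list alone, and camera called the list upward (adjusted p = 0.0134; adjusted p = 0.379 with an estimated correlation).

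Lists of growth and lipid synthesis genes pointed downward at 3 weeks. All 25 cell cycle genes lay below 0 (median -0.518), led by Mcm2, a subunit of the replicative helicase (-0.97 ± 0.27, SE), and Ccna2, cyclin A (-0.74 ± 0.27). The list score, the mean log2 difference from wild type, was -0.13, -0.02, -0.89 and -0.83 in the 4 Sel1L-deficient livers, so replicates 3 and 4 carried this shift. Fatty acid synthesis genes had a median of -0.594, with Elovl6 at -1.11 ± 0.37 and Scd1 at -0.85 ± 0.30, and PPARalpha targets one of -0.289, with Hadhb at -0.42 ± 0.12. CREBH-type targets had a median of -0.153 (G6pc -0.70 ± 0.29), gluconeogenesis and glycogen genes one of -0.202 (Gys2 -0.78 ± 0.34), and fetal and neonatal liver genes one of -0.196, of which Mest (-0.93 ± 0.20) fell adjusted over the list alone. In the other 5 of these 6 lists, 0 members passed either adjustment. Replicates 3 and 4 carried most of these shifts too, with scores of -0.26, -0.31, -0.87 and -0.73 for fatty acid synthesis, -0.14, 0.08, -0.72 and -0.52 for PPARalpha targets, and 0.09, 0.14, -0.44 and -0.44 for CREBH-type targets. For gluconeogenesis they were -0.07, 0.09, -0.41 and -0.25, and for fetal genes 0.07, -0.09, -0.64 and -0.62. Camera called all 6 (adjusted p = 1.44e-09, 3.02e-07, 0.000114, 0.0179, 0.0114 and 0.0266 in this order). With an estimated correlation the adjusted p was 0.379, 0.379, 0.379, 0.478, 0.379 and 0.426.

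Markers of other liver cells were lower beside these lists. Kupffer cell and macrophage markers had a median of -0.327 (Marco -1.08 ± 0.39, SE), stellate cell markers one of -0.203 (Ecm1 -0.33 ± 0.10) and sinusoidal endothelial markers one of -0.196 (Lyve1 -0.49 ± 0.14). Monocyte and neutrophil markers had a median of -0.156, extracellular matrix genes one of -0.243 (Tgfb1 -0.53 ± 0.16) and erythroid markers one of -0.268. Of the erythroid genes 3 fell adjusted over the list alone, among them Slc4a1, the red cell anion exchanger (-1.59 ± 0.32). Camera called these 6 lists (adjusted p between 0.000114 and 0.0179), and none with an estimated correlation (adjusted p = 0.379, 0.360, 0.379, 0.379, 0.593 and 0.198). Replicates 3 and 4 lay lowest in 3 of the 6, with scores of 0.24, -0.18, -0.35 and -0.40 for extracellular matrix (wild type -0.24 to 0.13), -0.01, -0.08, -0.20 and -0.28 for stellate and -0.02, -0.105, -0.24 and -0.27 for endothelial markers. Kupffer (-0.30, -0.39, -0.46 and -0.23) and erythroid scores (-0.29, -0.42, -0.49 and -0.38) were below every wild type in all 4. Bile duct (median -0.085) and lymphocyte markers (0.004) were not called, nor were cholesterol synthesis (-0.079), bile acid (0.145) and growth hormone axis genes (-0.100). The median levels of bile duct (3.54), lymphocyte (3.34) and monocyte and neutrophil markers (3) lay below the array medians. How far these marker lists follow the cells is therefore not known. Upward calls went to xenobiotic metabolism (median 0.272; Aldh1a1 0.74 ± 0.29) and acute phase genes (0.119; Orm1 1.35 ± 0.52), with adjusted p = 0.00143 and 0.00310, and adjusted p = 0.379 for each with an estimated correlation. The xenobiotic scores were -0.06, 0.08, 0.37 and 0.65, again higher in replicates 3 and 4. The acute phase scores were 0.475, 0.225, 0.135 and 0.168 against 0.03, -0.46 and 0.42 in wild type, so only replicate 1 lay above the wild-type range. That list was not called without wild-type replicate 2 (adjusted p = 0.352) or Sel1L-deficient replicate 1 (0.0988).

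Over all features, limma called 0 of 35556 at 3 weeks (smallest adjusted p = 0.186). At an unadjusted p under 0.05 there were 2634 features, 1388 higher and 1246 lower, where independent features without any effect would give 1778. The groups did not overlap for 7.4% of the 21218 features with 1 symbol, against 5.71% by chance. Camera called 18 of the 31 lists, 6 up and 12 down, and neither camera with an estimated correlation nor fry called any (0 lists each). In 6 of the 18 all 4 Sel1L-deficient scores lay beyond every wild-type liver in the called direction, and in the other 12 at least 1 did not. The calls of 9 of the 18 ended when 1 of the 13 livers was left out (CREBH-type, gluconeogenesis, xenobiotic, fetal, acute phase, p53, extracellular matrix, stellate and monocyte lists). Replicates 3 and 4, which carried many of these shifts, also had the least Sel1l (7.20 and 7.10). When only features with 1 symbol were tested, Derl3 rose (adjusted p = 0.0299) and Cd209f, a lectin gene named after its value was seen, fell (log2 difference -1.50, adjusted p = 0.0299). Without replicate 2 of the 3-week Sel1L-deficient livers 1 unnamed feature was called.

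The 9-week comparison asks the same in young adult liver, where 539 features changed, 367 up and 172 down. Among the named genes, most of the strongest falls were in male-biased liver genes, with the pseudogene Serpina4-ps1, given below, among them in size. Cyp4a12a, a testosterone-dependent fatty acid hydroxylase, fell from 10.42 ± 0.35 to 6.27 ± 1.40 (SD, n = 3 each; adjusted p = 0.0129). Hsd3b5, a steroid reductase, fell by 4.81 ± 0.90 on the log2 scale (SE), Cyp4a12b fell by 4.75 ± 0.74, Mup21, a urinary pheromone carrier, fell by 3.01 ± 0.47, and Cyp7b1, the oxysterol hydroxylase of bile acid synthesis, fell by 2.76 ± 0.54. Of the 19 measured male-biased genes 11 fell over all features and 14 adjusted over the list alone, all 19 lay below 0, and the median was -1.758. The female-biased list moved the other way (median 0.660): 5 of its 16 genes rose over all features and 6 adjusted over the list alone, among them Cyp2b9, a cytochrome P450 (3.23 ± 0.56), Hao2, a hydroxyacid oxidase (2.13 ± 0.29, from a wild-type level of 2.51, below the array medians, so a lower bound if that level is background), and Cyp3a44 (1.05 ± 0.18). Camera called both lists (adjusted p = 5.5e-18 and 2.22e-06), but not with an estimated correlation (adjusted p = 0.0994 and 0.0996 with an estimated correlation), and fry called both (adjusted p = 0.00436 and 0.00670). Within plate columns 5 and 7 the male-biased median was -1.18 and -2.57 and the female-biased median 0.46 and 0.87. These rest on 1 wild-type liver in column 5 and 1 Sel1L-deficient liver in column 7.

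Transcripts of the growth hormone axis, which sets sex-biased liver expression, were lower as a list, with 13 of 16 below 0. The activity of the axis was not measured, and a link to the sex-biased genes was not tested. Ghr, the growth hormone receptor, fell by 0.79 ± 0.13 and Igf1 fell by 0.53 ± 0.10 on the log2 scale (SE; adjusted p = 0.0196 and 0.0295), the 2 called members of 16, with 3 that fell adjusted over the list alone and a median of -0.348. The list was called by camera (adjusted p = 0.000582; adjusted p = 0.112 with an estimated correlation). Bile acid genes had a median of -0.286, and 1 of the 25 rose and 2 fell (2 and 6 adjusted over the list alone). Slco1a4, an organic anion uptake carrier, rose by 1.90 ± 0.31, and Cyp7b1 and Slc27a5, a bile acid-CoA ligase (-0.51 ± 0.10), fell. Camera called this list downward (adjusted p = 0.00886; adjusted p = 0.349 with an estimated correlation). Replicates 2 and 3 carried the call, with scores of -0.35 and -0.36, while replicate 1 (-0.05) lay within the wild-type range (-0.15 to 0.15).

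ER stress genes were higher at 9 weeks as well. Of 25 ER chaperones and folding enzymes 6 rose and 1 fell over all features (18 and 1 adjusted over the list alone), with a median of 0.568. Hspa5 rose from 10.51 ± 0.07 to 12.14 ± 0.56 (SD, n = 3 each; 3.10-fold), Creld2 rose 5.35-fold and Manf 3.40-fold, both secreted or ER-resident folding factors, and Pdia5, a disulfide isomerase, fell (-0.57). Of 28 ERAD components 3 rose: Derl3 (4.16 ± 0.77, SE), Syvn1 (1.70 ± 0.26) and Derl1 (0.58 ± 0.10), with 6 up and 1 down adjusted over the list alone and a median of 0.155. Of 29 ER translocation and transport genes Srprb (0.98 ± 0.12), a signal recognition particle receptor subunit, and Kdelr2 (0.63 ± 0.12), an ER retrieval receptor, rose, 13 adjusted over the list alone (median 0.304). Camera called these 3 lists (adjusted p = 2.06e-12, 1.52e-05 and 2.18e-12), fry too (adjusted p = 0.0164, 0.0189 and 0.0189), but camera with an estimated correlation did not (adjusted p = 0.241, 0.251 and 0.241 with an estimated correlation). Replicate 1 of the Sel1L-deficient livers had a chaperone list score of 0.28, against 0.98 and 1.00 in the other 2.

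Targets of the integrated stress response rose at this age: 4 of 27 over all features and 12 adjusted over the list alone (median 0.239). Nupr1 rose from 5.51 ± 0.35 to 9.07 ± 0.64 (SD; 11.8-fold), Trib3, a pseudokinase induced by ATF4 and CHOP, 3.97-fold, Ddit4 2.63-fold and Vldlr, a lipoprotein receptor, 2.63-fold. Among p53 targets 2 of 19 rose, Zmat3 (0.63 ± 0.11, SE) and Gadd45b (2.34 ± 0.48), with 10 up and 1 down adjusted over the list alone and a median of 0.465. Cdkn1a, the cell cycle inhibitor p21, stood at 5.77 ± 0.88 in wild type and 8.23 ± 0.84 in Sel1L-deficient liver (SD; adjusted p = 0.0944). Camera and fry called both lists (camera adjusted p = 1.72e-06 and 9.92e-05, fry 0.00251 and 0.00436; adjusted p = 0.0994 for each with an estimated correlation). Respiratory chain genes had a median of -0.233, with 0 of 24 called over all features and 11 that fell adjusted over the list alone, among them Cox5a (-0.31 ± 0.07). That list was called downward (camera adjusted p = 6.91e-08; fry 0.00962; adjusted p = 0.241 with an estimated correlation).

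In lipid metabolism, Cd36, a fatty acid uptake receptor, rose by 1.64 ± 0.23 and Acot2, an acyl-CoA thioesterase, by 2.21 ± 0.48 (SE), 2 of the 21 PPARalpha targets (median 0.148; 4 adjusted over the list alone). Of 18 CREBH-type targets 1 rose, Apcs, serum amyloid P (1.81 ± 0.26; adjusted p = 0.0123), and 2 adjusted over the list alone, Apcs and Fgf21. That list was not called (camera adjusted p = 0.626), and its median (-0.081) and mean (0.375) differ in sign. Cholesterol synthesis genes had a median of 0.323, with 0 of 19 called over all features and 5 that rose adjusted over the list alone, led by Fdps (0.95 ± 0.23). Fatty acid synthesis genes had a median of -0.536, with 1 that rose (Pparg, 0.83 ± 0.19) and 1 that fell (Mlxipl, -0.70 ± 0.16) adjusted over the list alone. The scores of the 3 Sel1L-deficient livers were 0.93, 0.24 and -0.04 for cholesterol synthesis, carried by replicate 1 (wild type up to 0.21), and -0.02, -0.74 and -0.52 for fatty acid synthesis, carried by replicates 2 and 3. Camera called the PPARalpha, cholesterol and fatty acid synthesis lists (adjusted p = 0.00223, 0.00219 and 0.00225), but none with an estimated correlation (adjusted p = 0.470, 0.509 and 0.431). Gluconeogenesis and glycogen genes were not called (median -0.194; camera adjusted p = 0.0536), and 3 fell adjusted over the list alone, among them Pygl, liver glycogen phosphorylase (-0.87 ± 0.20).

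Further genes with large rises were Cyp2a22, a cytochrome P450 (3.42 ± 0.56, SE), Serpina7, thyroxine-binding globulin (2.81 ± 0.31), Cgref1 (2.71 ± 0.49), Mmp12, macrophage elastase (2.52 ± 0.25, from 3.51, with the same limit as Hao2), and Slc22a27, an organic anion transporter (2.46 ± 0.29). Large falls were also seen in Cabyr (-2.60 ± 0.45) and in the pseudogenes Serpina4-ps1 (-4.47 ± 0.96) and Adh6-ps1 (-2.38 ± 0.45). The adjusted p of these 8 genes lay between 0.00523 and 0.0476. All 25 cell cycle genes but 1 lay above 0 (median 0.368; camera adjusted p = 1.99e-05; adjusted p = 0.415 with an estimated correlation), and 0 passed over all features or adjusted over the list alone. Markers of Kupffer (median 0.042), stellate (0.132), endothelial (-0.029, mean 0.007) and bile duct cells (-0.092, mean 0.031) were not called at 9 weeks (median and mean of the last 2 differ in sign), and the Kupffer list score was -0.58, 0.35 and 0.37 in the 3 Sel1L-deficient livers. The bile duct markers had a median level below the array medians, as given above.

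Secreted and immune genes were lower at 9 weeks in other lists. Plasma proteins made by hepatocytes had a median of -0.118, with 0 of 31 called over all features and 1 up and 6 down adjusted over the list alone, such as F9, a clotting factor (-0.50 ± 0.14, SE). Interferon-stimulated genes had a median of -0.325, and 1 of 25, Psmb8, an immunoproteasome subunit (-0.80 ± 0.19), fell adjusted over the list alone. Lymphocyte (median -0.122), monocyte and neutrophil (-0.192) and erythroid markers (-0.194) were lower, and of the last Car1, a red cell carbonic anhydrase, fell (-1.89 ± 0.32). The lymphocyte and the monocyte and neutrophil markers had median levels below the array medians, with the limit given at 3 weeks. Camera called these 5 lists downward (adjusted p = 7.70e-05, 0.000542, 0.0134, 0.0466 and 0.0381), but none with an estimated correlation (adjusted p = 0.352, 0.470, 0.267, 0.431 and 0.267). Acute phase (median -0.115), xenobiotic metabolism (0.076), fetal (0.007), extracellular matrix (-0.130), autophagy and lysosome (0.082) and circadian clock genes (0.022, mean -0.084, test downward) were not called.

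Of the 539 called features 406 had 1 symbol, 275 up and 131 down, the other 133 had several or none listed, and 4941 passed an unadjusted p under 0.05. Camera called 19 of 31 lists (9 up, 10 down), fry 11 and camera with an estimated correlation 0. In 12 of the 19 all 3 Sel1L-deficient scores lay beyond every wild-type liver in the called direction. In the other 7 (PPARalpha, fatty acid synthesis, cholesterol, bile acid, interferon, lymphocyte and monocyte lists) 2 of the 3 did. The calls of 6 ended when 1 of the 13 livers was left out (cholesterol, bile acid, interferon, lymphocyte, monocyte and erythroid lists). The count rests on the variance shared between groups: a fit of the 6 livers of this age alone called 1 feature (Adh6-ps1), with all 539 calls at an unadjusted p under 0.05 and the same sign. It was 1178, 30 and 18 without Sel1L-deficient replicate 1, 2 or 3 of this age, 140, 80 and 219 without wild-type replicate 1, 2 or 3, and 352, 359 and 317 without 3-week Sel1L-deficient replicate 1, 2 or 4. It was 1106 with array weights and 294 with plate column as a covariate.

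**Figure D2:**
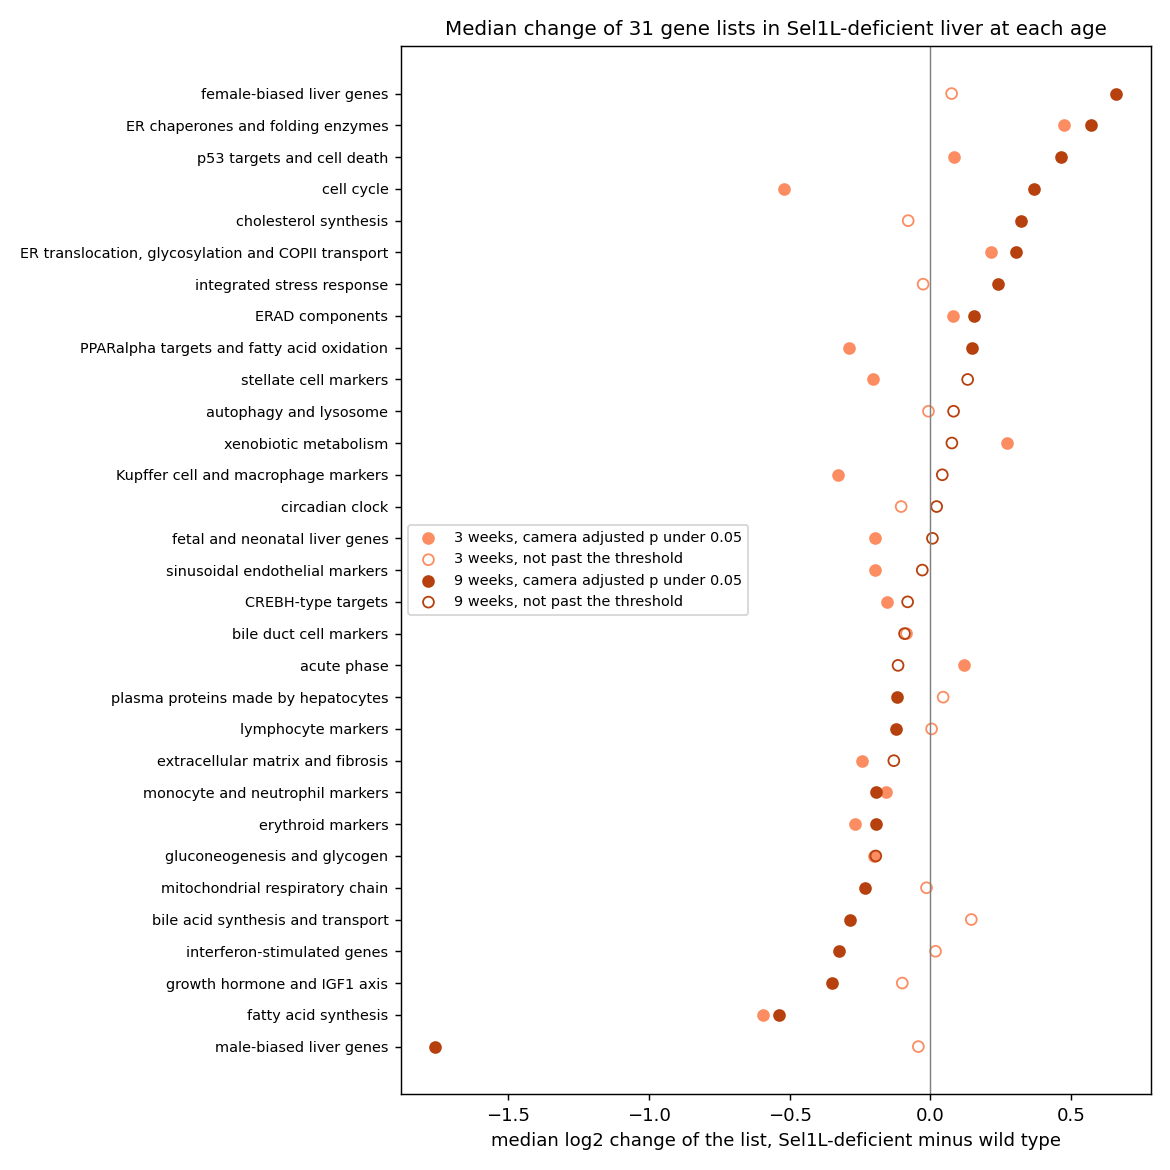
Median log2 change of the 31 gene lists (y axis) in Sel1L-deficient against wild-type liver (x axis), at 3 weeks (light) and 9 weeks (dark). Filled circles passed camera's threshold at the preset correlation; no list did with an estimated one. ER chaperones lay at 0.475 and 0.568, cell cycle genes at -0.518 and 0.368.

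Whether the effect of Sel1L deficiency differs between the ages was tested by the interaction. The male-biased list differed most, by a median of -1.769 log2 units at 9 relative to 3 weeks, with 14 of 19 genes lower adjusted over the list alone, among them Mup21 (-3.32 ± 0.64, SE) and Cyp4a12a (-4.03 ± 0.84). Camera called the list (adjusted p = 2.09e-16), but not with an estimated correlation (adjusted p = 0.189 with an estimated correlation). At 3 weeks the same list had a median of -0.043 and a mean of 0.071 (camera adjusted p = 0.787), when Cyp4a12a stood at 3.32 ± 0.54 in wild type and 3.21 ± 0.71 in Sel1L-deficient liver (SD). Those levels lie below the array medians of 3.72 to 3.81, and the table gives no background level, so how far they follow the transcript is not known. The female-biased list differed by 0.802 (3-week median 0.075; adjusted p = 0.304 with an estimated correlation), with Hao2 at 2.66 ± 0.40, which rests on the same low 9-week level. The cell cycle list differed by 0.820 (adjusted p = 0.304 with an estimated correlation), with 10 of 25 genes higher adjusted over the list alone, such as Mcm6 (1.72 ± 0.37). Its 3-week side was carried by replicates 3 and 4, as above. The integrated stress response differed by 0.280, with 5 higher adjusted over the list alone, such as Slc3a2 (0.81 ± 0.20; adjusted p of the list = 0.180 with an estimated correlation). ER chaperones did not differ by this test (median 0.090; camera adjusted p = 0.378), nor did ERAD components (0.116; 0.117).

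For single genes limma called 0 features in the interaction (smallest adjusted p = 0.0911; 3459 at an unadjusted p under 0.05), so no gene is shown to respond differently at the ages. Fgf21 differed by 2.78 ± 0.97 (SE; adjusted p = 0.408) and Syvn1 by 1.15 ± 0.36 (adjusted p = 0.364). Camera called 18 lists, 10 up and 8 down, a count that 6 of 100 splits of the livers reached, the real one included. With an estimated correlation it called 0, and fry called 2, the stress response and male-biased lists (adjusted p = 0.0327 and 0.0393). With only features of 1 symbol tested, 15 features were called, and without 9-week Sel1L-deficient replicate 1, 36. No feature was called at both ages (0; limma, all features), and with features of 1 symbol only Derl3 was. Of the 539 calls at 9 weeks 382 (70.9%) had the same sign at 3 weeks, against 53% of all features: 286 of the 367 higher calls, but 96 of the 172 lower ones, not far from that share. The median ratio of the 3-week to the 9-week change over the 539 was 0.153. The 539 were selected by their 9-week change in the same data, which by itself pulls this ratio towards 0. Over 18820 genes, which are not independent replicates, the changes at the ages correlated at 0.163, and the comparisons shared no arrays.

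**Figure D3:**
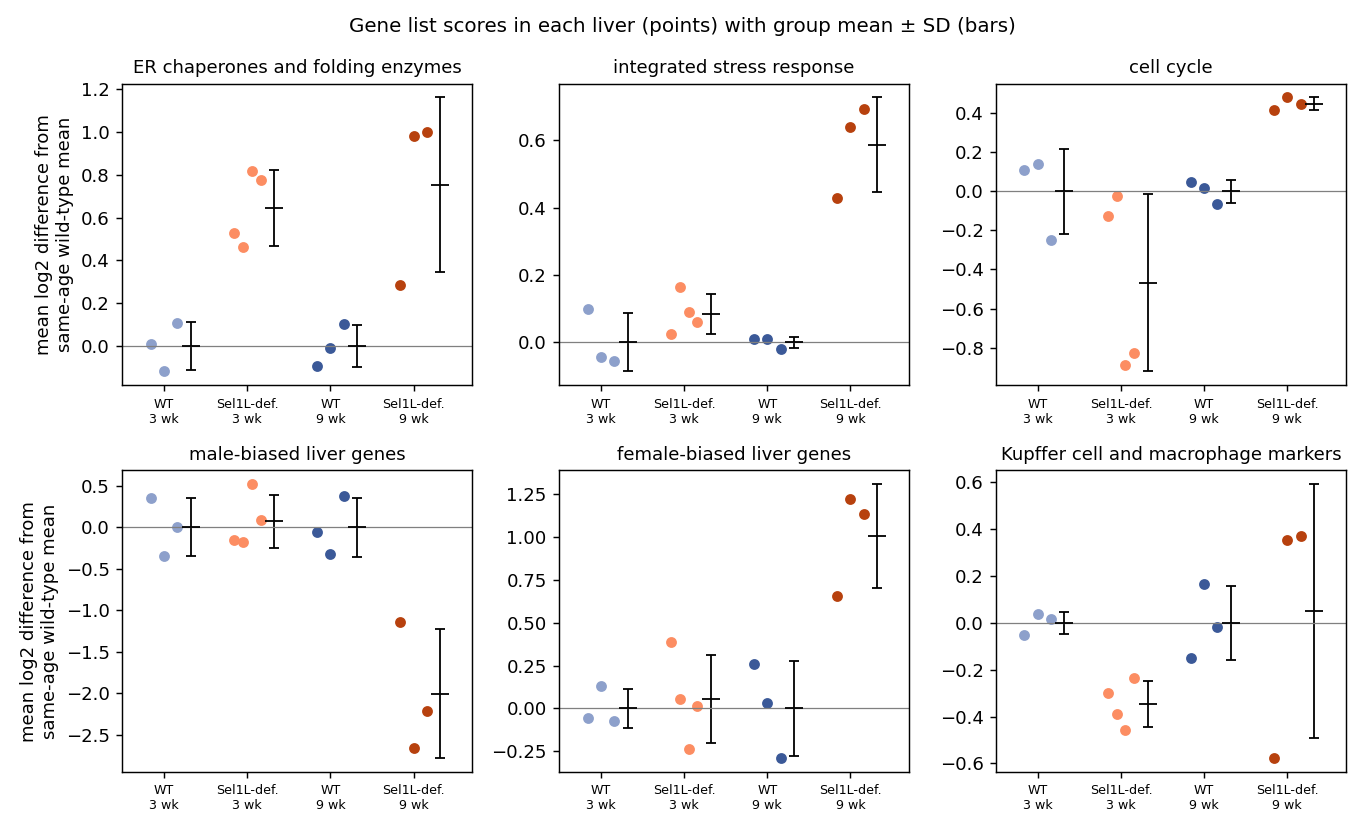
Scores of 6 gene lists (y axis, mean log2 difference from the wild-type mean of the same age) in each liver (points) of the 4 groups (x axis), with mean ± SD beside them. Male-biased genes were below wild type in all 3 Sel1L-deficient livers at 9 weeks (-1.15, -2.66 and -2.21), and the cell cycle score was -0.89 and -0.83 in 2 of the 4 at 3 weeks.

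Wild-type ageing from 3 to 9 weeks gives the background for these differences. Male-biased genes rose and female-biased genes fell: 16 of 19 and 8 of 16 over all features, 17 and 12 adjusted over the list alone, with medians of 2.906 and -1.623. Cyp4a12a rose by 7.09 ± 0.61 (SE), Cyp4a12b by 7.02 ± 0.74, Slco1a1, an organic anion carrier, by 6.13 ± 0.77, Hsd3b5 by 5.29 ± 0.90, Mup21 by 4.69 ± 0.47 and Serpina4-ps1 by 4.57 ± 0.96. Akr1c18, a hydroxysteroid dehydrogenase, fell by 5.23 ± 0.79, Hao2 fell by 5.21 ± 0.29, Slc22a27 fell by 4.80 ± 0.29, Cyp2b13 fell by 4.70 ± 0.77, Cyp2a22 fell by 4.54 ± 0.56 and Cyp2b9 fell by 4.26 ± 0.56. Of these genes Cyp4a12a, Cyp4a12b, Slco1a1 and Mup21 started at 3.32, 3.23, 3.32 and 3.40, and Akr1c18, Hao2 and Cyp2b13 ended at 3.27, 2.51 and 2.19, below the array medians. Where such values are background, which the table does not show, these 7 differences are lower bounds. Both lists were called by camera at the preset and at an estimated correlation (adjusted p = 0.036 each with an estimated correlation).

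Cell division and fetal programmes fell in wild type. Of 25 cell cycle genes 15 fell over all features and 23 adjusted over the list alone (median -1.526), such as Ccna2 (-2.50 ± 0.29) and Plk1, a mitotic kinase (-1.92 ± 0.22, to 3.59, below the array medians). Of 19 fetal and neonatal genes 5 fell (7 adjusted over the list alone; median -0.615), such as Igf2bp3 (-2.43 ± 0.22) and Gpc3 (-3.42 ± 0.51). Cholesterol synthesis genes fell, 3 of 19 over all features and 13 adjusted over the list alone (median -0.896), with Srebf2, their main regulator, at -0.77 ± 0.14. Camera called these 3 lists (adjusted p = 1.61e-29, 1.37e-08 and 5.70e-12), but not with an estimated correlation (adjusted p = 0.0682, 0.0904 and 0.306). Of the endothelial markers Lyve1 (-1.14 ± 0.15), Stab2 and Oit3 fell (median -0.261; camera adjusted p = 0.000163; adjusted p = 0.372 with an estimated correlation).

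In all, 672 features changed with age in wild type, 272 up and 400 down (limma; 4841 at an unadjusted p under 0.05), and camera called 12 lists, 2 of them with an estimated correlation, and fry 8. The count was 321, 414 and 366 without 3-week wild-type replicate 1, 2 or 3, 376, 296 and 298 without 9-week replicate 1, 2 or 3, and 255 in a fit of these 6 livers alone.

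In Sel1L-deficient liver, 55 features changed from 3 to 9 weeks, 27 up and 28 down (limma; 3580 at an unadjusted p under 0.05). Of the male-biased genes Mup20 rose (2.89 ± 0.42, SE; 8 of 19 adjusted over the list alone; median 0.657), and of the female-biased genes Hao2 (-2.55 ± 0.27) and Cyp3a44 (adjusted p = 0.0477) fell (5 of 16 adjusted over the list alone; median -0.837). Igf2bp3 (-2.28 ± 0.20) and Mest (-1.22 ± 0.20), fetal genes, fell, and Mmp12 rose (2.45 ± 0.23, from 3.58, below the array medians). Akr1d1, a steroid reductase of bile acid synthesis, fell by 1.16 ± 0.19. Respiratory chain genes fell, 16 of 24 adjusted over the list alone and 0 over all features (median -0.242), such as Cox5a (-0.30 ± 0.07). Camera called 17 lists, 7 up and 10 down, fry 6, and 0 with an estimated correlation (adjusted p = 0.252, 0.153, 0.157 and 0.157 for the male-biased, female-biased, fetal and respiratory lists). The difference between the genotypes' ageing is the interaction given above.

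In place of 55, 35 features were called after median centring, 21 up and 14 down, and the count was 90 without dim features, 144 with features of 1 symbol, 151 with array weights, 18 with plate column and 9 in a fit of these 7 livers alone. It was 8, 32 and 16 without 3-week Sel1L-deficient replicate 1, 3 or 4, 210, 19 and 6 without 9-week replicate 1, 2 or 3, and 27, 29 and 20 without 3-week and 15, 22 and 27 without 9-week wild-type replicate 1, 2 or 3.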

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

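The tests for female livers, for the shares of hepatocytes and of other cells and for the age position of single gene classes, and the splits of the livers, were chosen only after the results were seen. The 2 main tests of age position were not, but each was read with a further condition, given below, that its rule set beforehand did not hold.

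The interaction test called 18 lists for a difference between the ages in the effect of Sel1L deficiency (camera at the preset correlation, none with an estimated one). Of 100 splits of the livers 6 reached that count, the real one included (highest other 19), so chance is not excluded. Besides the real one, some of these 6 kept the 9-week genotype groups and so hold part of the effect. The share is thus an uncertain measure of chance. The values are medians of the 9-week minus the 3-week log2 change. Higher at 9 relative to 3 weeks were ER translocation (0.186), the integrated stress response (0.280), CREBH-type targets (0.234), PPARalpha targets (0.422), cholesterol synthesis (0.440), female-biased genes (0.802), the cell cycle (0.820), and Kupffer (0.412), stellate (0.218) and endothelial markers (0.121). Lower were bile acid genes (-0.534), the growth hormone axis (-0.241), male-biased genes (-1.769), plasma proteins (-0.168), acute phase (-0.330), interferon-stimulated (-0.401) and respiratory chain genes (-0.231) and lymphocyte markers (-0.234).

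A single liver far from the 3 others of its group was seen for 5 of 129 genes and 0 of 32 list scores tested in the 3-week Sel1L-deficient group; chance gives about 1 in 20. These were Irf1 at 7.52 in replicate 3 (others 6.08 to 6.26), Ntrk2 at 3.21 in replicate 3 (2.79 to 2.83), Atp5o at 8.86 in replicate 3 (8.95 to 8.97), Pth1r at 5.95 in replicate 3 (5.90 to 5.91) and Stard4 at 6.94 in replicate 4 (7.12 to 7.15).

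At 9 weeks male-biased genes were lower and female-biased genes higher in Sel1L-deficient liver. The tables argue against female livers, since the lowest mean of Y-linked genes in a Sel1L-deficient liver was 0.06 log2 units above the lowest in wild type and Xist lay between 1.71 and 2.64 in all 13 livers. A lower share of hepatocytes does not account for the size of the male-biased fall. That median lay further down than that of the 8 plasma proteins no brighter than the brightest male-biased gene (difference -1.329, robust SE 0.27 over genes, which are not independent). In each 9-week Sel1L-deficient liver the male-biased score (-1.15, -2.66 and -2.21) also lay below the score of all 31 plasma proteins (-0.06, -0.20 and -0.22). These 31 had a median level of 11.93 and reached 13.3, near the top of the scale (13.62). A loss can be compressed there, so their score adds no separate support. Each of the 8 plasma proteins was lower, though (median -0.429), so a smaller loss stays open. A general delay of maturation may account for part and stays open. Over the age-changed genes outside the sex-biased lists the 9-week Sel1L-deficient livers stood at a median of 0.593 of the wild-type course (0 for 3 weeks, 1 for 9). The lowest left-out wild-type liver stood at 0.825. The 3 Sel1L-deficient livers stood at 0.489, 0.314 and 0.356 for rising and 0.682, 0.595 and 0.7 for falling genes. A median below that wild-type liver was the outcome set beforehand for a delay. Agreement of the single classes was a further condition, not part of that rule. Only members of the 2 lists were left out, so other sex-biased genes can remain in this set. Its position can therefore restate part of the sex-biased shift. Of the single classes, the 15 age-changed cell cycle genes were behind as well, at 0.739, 0.676 and 0.737 (wild type 0.941 to 0.961), which restates the higher cell cycle list of that age. Each wild-type liver was placed by a refit without it, on the fewer genes called there. At 9 weeks these were 9, 7 and 9 cell cycle genes and 3, 4 and 3 fetal genes. Outside the sex-biased lists they were 232, 186 and 187 genes in place of 426. The wild-type ranges therefore rest on other gene sets. The 5 fetal genes stood at 0.885, 0.98 and 1.079, close to wild type (0.908 to 1.083). Of these, Gpc3 and Cyp3a16 (2.92) lay below the array medians in wild type then, and Cyp3a16 is also in the female-biased list. So few genes cannot decide for or against a delay.

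At 3 weeks all 25 cell cycle genes were lower. The cell cycle median lay below that of Kupffer, stellate and endothelial markers (difference -0.278, robust SE 0.077 over genes, which are not independent). In replicates 3 and 4 the cell cycle scores (-0.89 and -0.83) lay below all 3 marker scores (lowest -0.46 and -0.28). A lower share of these cells does not account for the size there. In replicates 1 and 2 the cell cycle scores (-0.13 and -0.02) lay above the Kupffer scores (-0.30 and -0.39), though in replicate 1 below the stellate and endothelial ones (-0.01 and -0.02). For replicates 1 and 2 a lower share stays open. Loss of a single cycling type, such as erythroid progenitors, stays open. Livers further along the course to 9 weeks stay open too. Over genes that rise with age the Sel1L-deficient livers stood at a median of 0.145 (SD 0.125), below the highest wild-type liver (0.2). The rule set beforehand counts such a median against this explanation. The gap to that wild-type liver was smaller than the SD, a further condition that was not part of the rule. Replicates 3 and 4, whose cell cycle scores were lowest, stood at 0.281 and 0.220. Falling genes, which include cell cycle genes, put the 4 livers at 0.115, 0.15, 0.45 and 0.398 (wild type up to 0.247). Fetal genes put them at -0.081, -0.024, 0.451 and 0.299 (wild type up to 0.042). In each of these classes replicates 3 and 4 were ahead of every wild-type liver, and replicates 1 and 2 were not. The wild-type livers were again placed by refits without them, on fewer genes. With 4 livers that differ this much, the explanation could hold for 2 of them and cannot be told apart from chance.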

How the results depend on the processing

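No alternative was chosen only after the result was seen. Of the values of named genes under the alternatives, 14047 stayed on their side of the threshold with no called change of sign, 580 kept the direction and lost the call, 186 gained one and 0 reversed. Most of the 14047 belong to genes not called in the main fit, which had no call to lose. Named genes called there numbered 0 at 3 weeks, 42 at 9 weeks and 0 in the interaction. For ageing they numbered 51 in wild type and 7 in Sel1L-deficient liver. The 580 are to be read against these calls. Of the 3-week count, 0 became 2 with only features of 1 gene symbol tested, the interaction count 15 and the both-ages count 1; fewer features were tested and the prior degrees of freedom were 3.67 in place of 2.22. That setting took the 55 features of Sel1L-deficient ageing to 144, the filter on dim features to 90, and median centring to 35 (21 up, 14 down in place of 27 and 28). A fit of the compared groups alone called 1 feature at 9 weeks in place of 539, 255 in place of 672 for wild-type ageing and 9 in place of 55; fewer samples set the variance (6.04 in place of 11.22 degrees of freedom at 9 weeks). It cannot be made for the interaction, which needs all 4 groups. Array weights gave 1106 at 9 weeks and 151 for Sel1L-deficient ageing, plate column 294 and 18, and an adjusted p under 0.01 28 and 6, with 168 for wild-type ageing. The fit with a replicate block gave 184 at 9 weeks (170 shared with the 539), 440 and 12 for ageing in wild-type and Sel1L-deficient liver. In their deviations from the group means, livers of the same number correlated between -0.024 and 0.096, and those of different numbers between -0.126 and 0.073. In wild-type ageing the same-number pairs (0.039 to 0.073) lay above all others (-0.047 to 0.003). No strong pairing was seen, and a weak one is not excluded.

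List counts with an estimated correlation were 0 at 3 weeks, 0 at 9 weeks, 0 for the interaction, 2 for wild-type and 0 for Sel1L-deficient ageing, and with fry 0, 11, 2, 8 and 6, in place of 18, 19, 18, 12 and 17. Leaving out each liver in turn gave 0 to 1 features at 3 weeks (1 without Sel1L-deficient replicate 2), 18 to 1178 at 9 weeks (without Sel1L-deficient replicate 3 and 1), 0 to 36 for the interaction, 296 to 639 for wild-type and 6 to 210 for Sel1L-deficient ageing (6 and 210 without 9-week Sel1L-deficient replicate 3 and 1). The list counts then stayed between 14 and 19, 15 and 20, 13 and 19, 10 and 15, and 14 and 19. Renewed quantile normalization, trend and robust settings and a minimum fold of 1.5 left every gene count within 1.5 times and were not run for lists. For the dim filter, centring, array weights, plate column, block and left-out livers the cause was not tested. Signal over background limits the dim features, for which the table gives no detection call.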

Other observations

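The tests of residual Sel1l, plate column and array quality and the splits of the samples were chosen only after the results were seen.

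In wild-type liver, several further genes of transport and hormone response changed between 3 and 9 weeks. Slc10a2, the apical bile acid transporter, rose by 2.33 ± 0.42 on the log2 scale (SE), while Slco1a4 fell by 2.45 ± 0.31. Ghr rose by 0.81 ± 0.13 and Bcl6, a repressor of female-biased genes, by 2.20 ± 0.44. Orm1, an acute phase protein, rose by 3.31 ± 0.55, and the metallothioneins Mt1 and Mt2 fell (-0.88 ± 0.15 and -1.66 ± 0.28). Asns, asparagine synthetase, fell by 2.39 ± 0.40. Of the basement membrane genes Col4a1, Col4a2 and Sparc fell, 3 of 23 extracellular matrix genes (median -0.404; camera adjusted p = 3.22e-05; adjusted p = 0.503 with an estimated correlation).

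The response differed between Sel1L-deficient livers of one group: the ER chaperone score was 0.53, 0.46, 0.82 and 0.78 at 3 weeks and 0.28, 0.98 and 1.00 at 9 weeks. The tables argue against plate column at 3 weeks, where column means differed by 0.054 and livers within a column by at least 0.286, a ratio of 0.19. A poor array stays open at both ages: the liver with the lowest score correlated at 0.9842 (3 weeks) and 0.9825 (9 weeks) with wild-type arrays of its age, but a weaker response raises that value too. Against it, the 3-week liver had the weight of its group (1.02, others 1.02 to 1.11) and correlated at 0.9873, 0.9837 and 0.9842 within it (other pairs 0.984 to 0.9868), while the 9-week liver had the lowest weight (0.62) and correlated at 0.9836 with its own group, where the other 2 reached 0.9884. Residual Sel1l cannot be told apart from chance: over the 7 livers, with age means removed, Sel1l and the score correlated at -0.568 (exact permutation p = 0.111; Spearman -0.5, permutation p = 0.111; -0.697 without the 2 farthest livers; adjusted permutation p = 0.444 over 4 relations tested), and at 0.857 with the cell cycle score (permutation p = 0.333), 0.732 with Fgf21 (permutation p = 0.306) and -0.222 with the stress response score (permutation p = 0.528), and each plate column holds too few livers of an age for its own value.

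The same livers were split in other ways to see how often chance gives such counts, with 35 splits at 3 weeks and for ageing in Sel1L-deficient liver, 10 at 9 weeks and for wild-type ageing, and 100 for the interaction and for calls at both ages. At 3 weeks all 35 splits reached the real count of 0 genes (highest other 1), as any split must, so this says nothing about chance. For features at an unadjusted p under 0.05 chance is not excluded (4 of 35; real 2634, highest other 3349). For lists only 1 of 35, the real one, reached 18, but another split reached 17, and 0 of the 18 hold with an estimated correlation or with fry. That share, 0.0286, is the smallest that 35 splits can give, and it was not adjusted over the split tests. Chance is therefore not excluded for that count. At 9 weeks the splits are too few: 1 of 10 for genes (real 539, highest other 0) and 1 of 10 for lists (real 19, highest other 18). For wild-type ageing they are too few as well: 1 of 10 for genes (real 672, highest other 0) and 3 of 10 for lists (real 12, highest other 15). For ageing in Sel1L-deficient liver only the real split of 35 reached the gene count (real 55, highest other 2). This argues against chance for genes, but again at the smallest share possible and without adjustment, so it does not exclude it. For lists chance is not excluded either (4 of 35, real 17, highest other 18).

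For the interaction chance cannot be excluded for lists (6 of 100 with the real one included, real 18, highest other 19). Some of the other splits that reached 18 kept the 9-week genotype groups and so hold part of the effect, which makes this share uncertain. For genes all 100 of 100 splits reached the real count of 0 (highest other 98), as any split must, which says nothing about chance. The split with 98 kept the 9-week genotype groups and mixed the 3-week livers; it was 1 of 8 splits besides the real one that kept these groups, 6 of them with calls, while 91 mixed them, 3 with calls and at most 2 each. For calls at both ages all 100 of 100 splits reached the real count of 0 (highest other 0), which says nothing either.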
